A study of Sus scrofa with 22 samples.

How the data were processed

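Small RNA was sequenced from subcutaneous fat of 22 female pigs of 6 months, of the breeds Pietrain, Large White and Hampshire, whose fat the labels class as thick or thin. Per the labels' protocols, tissue was kept in RNAlater after slaughter, RNA had an integrity number above 7.5, libraries were made with a NEBNext small RNA kit and size-selected on a polyacrylamide gel, and an Illumina HiScan SQ read 36 cycles from 1 end. The submitters' processing notes name bcl2fastq, FastQC, DESeq2 and the pig assembly Sscrofa10.2. The read trimmer, the aligner, the miRNA annotation release and any version were not given in the sources used here. No coordinates are given, because the annotation at hand was of another assembly than the one in those notes.

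The authors deposited, for each breed separately, a table of read counts per sequence, with a pig miRNA name for all but 80 of 8489 sequences and with no normalization. Sequences were 17 to 25 nt long, and the tables held 7039 sequences in Pietrain, 6796 in Large White and 5391 in Hampshire. The smallest count above 0 was 6 in every library, so a 0 in these tables can stand for up to 5 reads of a sequence, and no limit is set on a value of 0. The authors also deposited 1 DESeq2 comparison of fat classes per breed, whose columns are, per the file headers, a mean signal over libraries, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. The sign of the deposited log2 fold change was found from the values to be thin minus thick.

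Counts of all sequences of 1 mature miRNA name were summed, which gave 250 names over the 3 tables, 191 of them in every table. The unnamed sequences held 0.0480% of reads and stayed out of library sizes and tests. Library totals ranged from 431542 to 3137757 reads. PCR reads without molecular identifiers are not independent molecules. Of 32 pairs of libraries within groups, all of different animals, the lowest chi-square per degree of freedom was 171, so none of these pairs agreed within sampling noise. The labels do not pair libraries across groups.

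The main test was edgeR 4.0.16's quasi-likelihood test (robust, with limma 3.58.1 in R 4.3.3) after TMM scaling and a filter that kept names with a count of about 10 in the smallest group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Thick and thin fat were compared within each breed alone, over all breeds with breed as a term, and in a test of whether the fat difference varied between breeds. Breeds were compared with thick and thin fat weighted equally. A standard error is the fitted log2 fold change divided by the square root of the F value, and intervals are 95% from the moderated degrees of freedom. CPM values are counts (CPM) scaled to TMM library sizes over all 22 libraries. P-values measure the spread between these libraries, and the labels do not say whether libraries of different breeds were prepared or sequenced together.

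Before the data were examined, 20 lists of miRNAs were fixed: adipogenesis promoters, adipogenesis repressors, thermogenic adipocyte, lipid and cholesterol metabolism, the let-7, miR-29 and miR-30 families, the miR-17-92 cluster and paralogs, the miR-23/24/27 clusters, the DLK1-DIO3 imprinted cluster, markers of skeletal muscle, red blood cells, leukocytes, endothelium, smooth muscle and stroma, epithelium and skin, liver and nerve, and miRNAs linked to hypoxia, stress and p53 or to inflammation. Lists share members. They were tested with limma's camera at a preset correlation of 0.01 where 3 or more members were measured, with adjustment over lists. The named miRNAs followed a rule fixed at the same time: the 8 of smallest p per direction among those past the threshold, or the 5 of smallest unadjusted p per direction where fewer than 5 passed in a comparison of fat classes, and the 5 most abundant miRNAs over all breeds.

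A miRNA was counted as lost in a library when its count there was 0 although at least 100 were expected from its median CPM in libraries with reads. This definition was chosen after seeing the data, and 36 names met it in at least 1 library. No fold is given for these miRNAs against a group whose libraries were all at 0. Alternatives were other scalings, no filter and a stricter filter of 10 CPM, DESeq2 1.42.0, limma-voom with quality weights, the sequences as deposited, and leaving out each library in turn. A few more were added after the data were seen.

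The tests were checked on simulated counts in 10 runs, with 40 names per run changed 2-fold or 4-fold. Counts were drawn for the real miRNAs with their mean over all libraries of the fit and the real dispersions and library sizes. They held no other difference between groups and did not model losses in single libraries, so recovery in the real data may differ. For the interaction the change was made in Hampshire thick fat only. Over all breeds (182 miRNAs) the fat test recovered 52% of 2-fold and 72% of 4-fold changes. Within 1 breed the shares were 4% and 40.5% in Pietrain (161 miRNAs), 24% and 66.5% in Large White (170 miRNAs), and 0.5% and 4% in Hampshire (172 miRNAs). For Hampshire minus Large White they were 39.5% and 62.5%, for Hampshire minus Pietrain 40% and 60%, for Pietrain minus Large White 41.5% and 65.5%, and for the interaction 2.5% and 36.5%, each on 182 miRNAs. Of the calls made, 6.06% over all breeds were of unchanged names, above the 5% of the threshold, and 1 changed name there was called with the wrong sign. In the other comparisons the share of false calls ran from 0% in Hampshire to 4.89% for Pietrain minus Large White. The number changed was 40 in every comparison, kept low because 161 to 182 names were tested, and the test of single sequences was not checked on simulated data. The exchange of Large White libraries came from a search over splits, by log2 ratios of normalised means over sequences with reads in every library of a breed. An earlier form of that search over all sequences chose a split for Pietrain that did not match the deposited fold changes, and was replaced.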

Results

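The data are miRNA read counts from subcutaneous fat of 22 pigs. Pietrain contributed 4 libraries of thick and 3 of thin fat, Large White 4 and 4, and Hampshire 5 and 2. Totals ran from 759210 to 3137757 reads in Pietrain, from 558144 to 2731336 in Large White and from 431542 to 2315501 in Hampshire. miR-148a-3p was the most abundant miRNA, at 20.1% ± 5.41 of reads (SD, n = 22), followed by miR-143-3p at 9.11% ± 3.46 (SD, n = 22). miR-26a, miR-10b and miR-99a came next by mean CPM.

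Some abundant miRNAs were at 0 in single libraries. miR-21 had 32374 ± 6569 CPM (SD, n = 4) in Large White thin fat and was at 0 in Large White thick fat replicate 3. miR-199ab-3p had a median of 17139 CPM where its count was above 0 and was lost in 7 libraries, 3 of them Pietrain thick fat. miR-145-5p, a smooth muscle miRNA, was lost in 4 Hampshire libraries, both thin fat libraries among them. miR-214-3p had 1092 ± 298 (SD, n = 4) CPM in Large White thin fat and was at 0 in all 7 Hampshire libraries. In all, 36 miRNAs were lost in at least 1 library, and each library had lost between 4 and 20 of them.

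**Figure D1:**
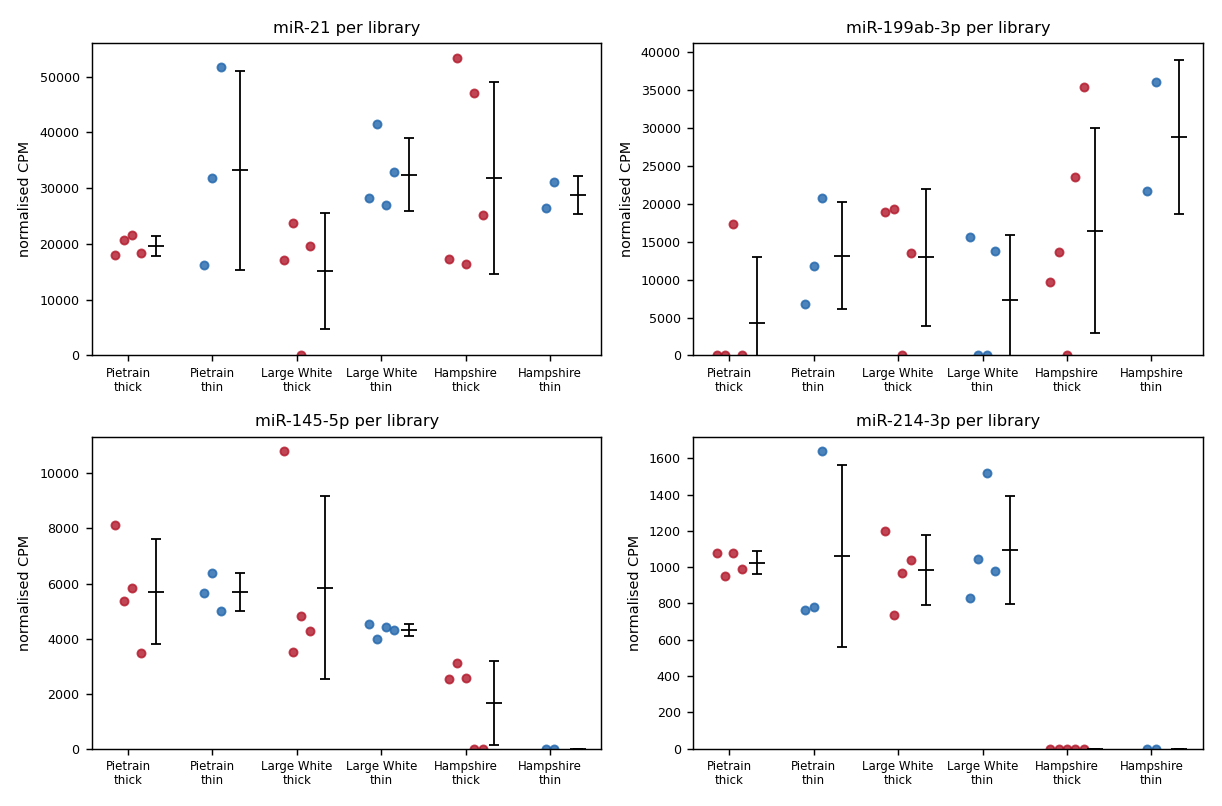
Normalised CPM (y axis, linear from 0) of miR-21, miR-199ab-3p, miR-145-5p and miR-214-3p in the 6 groups of breed and fat class (x axis). Points are libraries, and bars are the mean and SD of the group; miR-214-3p is at 0 in all 7 Hampshire libraries.

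Whether thick and thin fat differ in miRNA content was asked in each breed. In Pietrain, miR-7 averaged 526.1 ± 83.6 (SD, n = 4) CPM in thick and 932 ± 131 (SD, n = 3) CPM in thin fat, a log2 fold change (thick minus thin) of -0.79 ± 0.17 (SE), lower in 4 of 4 thick libraries. It did not pass the test (edgeR adjusted p = 0.482). let-7f-5p, at -0.37 ± 0.11, and miR-140-3p, at -0.58 ± 0.19, had the next smallest p-values, and miR-21 and miR-1468 completed the lower side. On the higher side miR-505 had 0.75 ± 0.30 and miR-99a 0.55 ± 0.25, followed by miR-9841-3p, miR-615 and miR-155-5p, none of them past the threshold. edgeR called 0 of 161 miRNAs, with 4 at an unadjusted p under 0.05. DESeq2 called 1, miR-7, with an adjusted p of 0.00697 in a range of 0.00697 to 0.995 over the alternatives, and limma-voom called 0. Without Pietrain thick fat replicate 3 edgeR called 2, miR-199ab-3p and miR-199b-5p. Both are lost in thick fat replicates 1, 2 and 4, all the thick libraries left in that fit, so these calls rest on losses. None of the fixed miRNA lists passed.

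For single sequences in place of summed miRNAs, edgeR called 65 in Pietrain, 29 higher and 36 lower in thick fat. The authors' deposited table called 89 sequences of 28 miRNAs there, 63 higher in thin and 26 higher in thick fat. Of these, 86 differed by 1 base from a sequence of the same miRNA and length that was at least 10 times as abundant, against 68.8% of all Pietrain sequences. In 49 of the 89 the mean count was 0 in 1 fat class, where a 0 can stand for up to 5 reads per library. 25 of the 26 higher in thick fat carried the change U1G, with positions counted from 1 at the 5' end. One was the let-7a sequence GGAGGUAGUAGGUUGUAUAGUU, with a deposited log2 fold change (thin minus thick) of -1.94. Over 20 abundant miRNAs, the median share of U1G reads was 0.758% ± 0.0338 (SD, n = 4) in thick and 0.247% ± 0.00735 (SD, n = 3) in thin Pietrain libraries. Reads with other first bases went the other way, with median shares of U1A of 0.0682% ± 0.0269 (SD, n = 4) in thick and 0.168% ± 0.00113 (SD, n = 3) in thin Pietrain libraries, and of U1C of 0.308% ± 0.0157 (SD, n = 4) and 0.416% ± 0.0176 (SD, n = 3). These shares were examined because of the calls in the same libraries, so no test of their difference is given. The median share of U1G over the 20 miRNAs was at most 0.0150% in each Large White library and 0% in each Hampshire library, where single miRNAs did have such reads. For miR-148a-3p the share was 0.0206% ± 0.00506 (SD, n = 4) in thick and 0.0226% ± 0.00574 (SD, n = 4) in thin Large White fat, and 0.0172% ± 0.00229 (SD, n = 5) and 0.0162% ± 0.00114 (SD, n = 2) in Hampshire, against 0.872% ± 0.0441 (SD, n = 4) and 0.280% ± 0.0206 (SD, n = 3) in Pietrain.

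**Figure D2:**
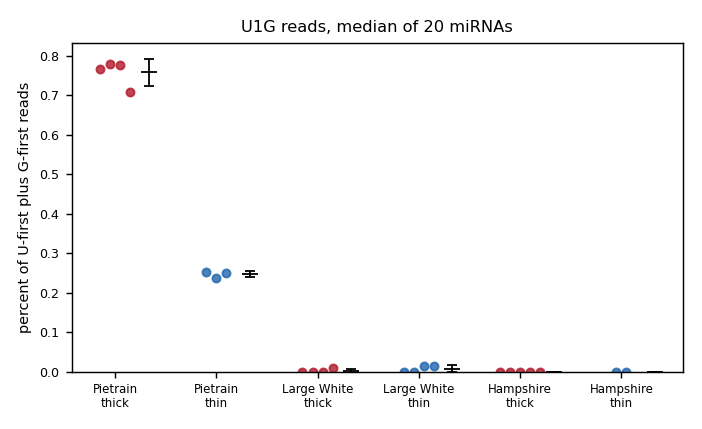
Median percent, over 20 abundant miRNAs, of reads with U1G among reads of the leading sequence and its U1G form (y axis, from 0) in the 6 groups (x axis). Points are libraries with the group mean and SD; Pietrain thick libraries lie between 0.708% and 0.779%, Pietrain thin libraries between 0.238% and 0.251%.

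In Large White, miR-184 averaged 32.0 ± 9.79 (SD, n = 4) CPM in thick and 16.2 ± 4.53 (SD, n = 4) CPM in thin fat (log2 fold change 1.00 ± 0.38, SE), higher in 4 of 4 thick libraries but not past the test (edgeR adjusted p = 0.958). miR-451, miR-151-3p, miR-27a-5p and miR-125b followed on the higher side. On the lower side stood miR-128, at -0.43 ± 0.19, then miR-146a-5p, miR-9, miR-148b-3p and miR-499-5p, all with an adjusted p of 0.958. edgeR, DESeq2 and limma-voom called 0 of 170 miRNAs, with 2, 3 and 3 at an unadjusted p under 0.05, and no list passed. Without Large White thick fat replicate 2, 1 was called, miR-500, a miRNA lost in 11 libraries. The labels and the authors' deposited table disagreed on these libraries: across sequences, a DESeq2 refit by the labels had r = -0.653 with the deposited fold changes, and one with thick replicate 1 and thin replicate 1 exchanged had r = -1.0. With that exchange, chosen after seeing the data, edgeR again called 0 miRNAs. On the log2 scale miR-9 then moved from -0.63 to 0.35, miR-128 from -0.43 to -0.082, miR-148b-3p from -0.25 to -0.0090 and miR-151-3p from 0.26 to 0.0016, while miR-184 stood at 0.81 and miR-451 at 0.51.

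In Hampshire, miR-9, a miRNA best known from the nervous system, averaged 83.4 ± 5.52 (SD, n = 5) CPM in thick and 220.3 ± 86.5 (SD, n = 2) CPM in thin fat, a log2 fold change of -1.35 ± 0.31 (SE), lower in 5 of 5 thick libraries (edgeR adjusted p = 0.515). miR-143-3p, which is abundant in adipocytes and smooth muscle, had -0.97 ± 0.35, and miR-100, miR-381-3p and miR-182 were the others on the lower side. miR-486, carried by red blood cells, had 1.22 ± 0.43 and miR-193a-5p 0.88 ± 0.34 on the higher side, with miR-6529. miR-145-5p and miR-145-3p were also there, at 0 in both thin libraries and in 2 of 5 thick libraries. edgeR called 0 of 172 miRNAs, with 5 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 3, miR-145-5p, miR-9 and miR-200b, the last of uncertain name because it shares sequences with miR-429, and the authors' deposited table called 1 sequence, of miR-145-5p. No list passed, and adjusted over the list alone 1 nerve marker, miR-9, was called. Thin fat had 2 libraries, and without replicate 2 of them 1 miRNA was called, miR-574-3p, lost in 5 libraries; the lone thin library is then assumed to vary like those of thick fat, which alone give the spread.

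Over all breeds, miR-9 had the smallest p. Its log2 fold change was -0.86 ± 0.20 (SE, 95% interval -1.28 to -0.44), and it was lower than the thin fat mean of its breed in 13 of 13 thick libraries. In Pietrain it averaged 49.5 ± 11.8 (SD, n = 4) CPM in thick and 76.0 ± 27.9 (SD, n = 3) CPM in thin fat, and in Large White 39.6 ± 14.4 (SD, n = 4) and 62.1 ± 19.7 (SD, n = 4) CPM. It missed the threshold (edgeR adjusted p = 0.0724) and lay at 0.00514 with DESeq2, within a range of 0.00514 to 1.0 over the alternatives. Without Pietrain thin fat replicate 3 or without Large White thick fat replicate 4 it passed, with edgeR adjusted p-values of 0.0212 and 0.0234 and log2 fold changes of -0.95 and -0.96. With the 2 Large White libraries exchanged it was -0.48 on the log2 scale, and edgeR again called 0. miR-450a, at -0.37 ± 0.18, and miR-7, at -0.32 ± 0.16, followed on the lower side, with miR-19a and miR-20b at under 22 CPM in every library. On the higher side were miR-505, at 0.40 ± 0.21, let-7d-3p, miR-139-5p, miR-378 and miR-326. The most abundant miRNAs did not pass the test, with fold changes on the log2 scale of -0.10 ± 0.12 for miR-148a-3p, -0.16 ± 0.26 for miR-143-3p, 0.06 ± 0.10 for miR-26a, 0.02 ± 0.11 for miR-10b and 0.14 ± 0.14 for miR-99a. With the exchange miR-143-3p was at -0.53.

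edgeR called 0 of 182 miRNAs over all breeds, with 3 at an unadjusted p under 0.05, DESeq2 called 1, miR-9, and limma-voom called 0. The interval of 98 miRNAs lay within a log2 fold change of 1 in either direction. Of the fixed lists, the miR-17-92 cluster and paralogs, miRNAs that promote cell proliferation, passed as lower in thick fat. Its 7 members had a median of -0.22, with miR-17-5p at -0.22 ± 0.16, miR-19b at -0.25 ± 0.18 and miR-92a at 0.07 ± 0.20, and 0 were called alone or adjusted over the list alone (camera adjusted p = 0.0187). With an estimated correlation its adjusted p was 0.202. With the 2 Large White libraries exchanged, added after seeing the data, its median was -0.081 and the call ended (camera adjusted p = 0.412). The other 16 lists tested had camera adjusted p-values of 0.879 or more, adipogenesis promoters and repressors, thermogenic, leukocyte and endothelial lists among them. The lists with 2 members had medians of -0.10 (miR-29 family) and -0.40 (nerve), and of the liver list miR-122 had -0.17 ± 1.36. Adjusted over the list alone, 1 nerve marker, miR-9, was called, and 0 members of the other lists.

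**Figure D3:**
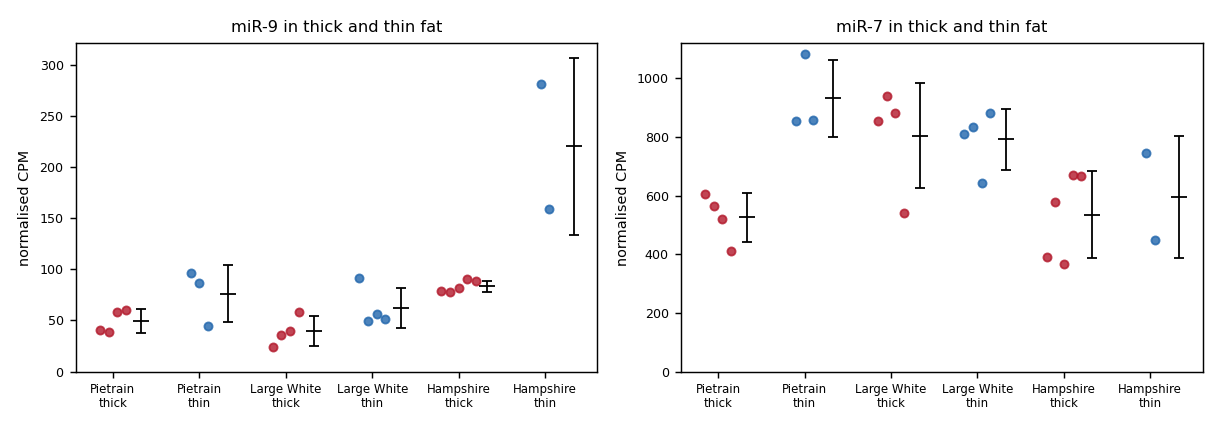
Normalised CPM (y axis, linear from 0) of miR-9 and miR-7 in thick and thin fat of 3 breeds (x axis). Points are libraries and bars the group mean and SD; mean miR-9 is lower in thick fat of each breed by the labels, and neither miRNA passed the edgeR test.

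Whether the fat difference varied between breeds was tested directly. edgeR called 0 of 182 miRNAs, with 10 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 2, miR-145-5p and miR-145-3p, which are lost in 4 Hampshire libraries. Between single pairs of breeds edgeR called 0, with 6 (Pietrain and Large White), 11 (Hampshire and Large White) and 12 (Hampshire and Pietrain) at an unadjusted p under 0.05. Without Hampshire thin fat replicate 2, 1 was called, miR-328. Without Hampshire thin fat replicate 1, and without the 2 libraries richest in miR-122, an alternative added after seeing the data, the calls were let-7a and let-7d-5p. Those 2 libraries include Hampshire thin fat replicate 1, so the 2 fits are not separate. Each of these fits without a thin library rests on 1 Hampshire thin library.

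Pietrain and Large White were compared in the same way as the other breeds. miR-20a had a log2 fold change (Pietrain minus Large White) of 0.62 ± 0.17 (SE) and a mean of 475 ± 117 (SD, n = 7) CPM in Pietrain and 305 ± 35.6 (SD, n = 8) CPM in Large White, higher in 7 of 7 Pietrain libraries. miR-486 had 0.83 ± 0.24 and miR-140-3p 0.44 ± 0.13, and all 3 had an edgeR adjusted p of 0.224. edgeR called 0 of 182 miRNAs, with 14 at an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 4, miR-20a, miR-486, miR-140-3p and miR-142-5p, the last of which is lost in 15 libraries. The miR-17-92 cluster and the red blood cell markers both had a camera adjusted p of 0.0703, and adjusted over the list alone 1 member of each was called, as was 1 adipogenesis promoter. Without Large White thick fat replicate 1, 1 miRNA was called, miR-140-3p. Breeds were deposited in separate tables and may coincide with library batches, so breed and batch cannot be told apart in this or the next comparisons.

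Hampshire fat differed from that of both other breeds in several miRNAs, miR-148a-3p, miR-27a, miR-32 and let-7e among them. miR-148a-3p, a promoter of adipogenesis, averaged 291033 ± 55524 (SD, n = 7) CPM in Hampshire against 166109 ± 34298 (SD, n = 8) in Large White and 164339.8 ± 21948 (SD, n = 7) in Pietrain. miR-27a, a repressor of adipogenesis, averaged 6818 ± 1304 (SD, n = 7), 3382 ± 517 (SD, n = 8) and 3696 ± 993 (SD, n = 7) CPM, and miR-32 averaged 283 ± 104 (SD, n = 7), 94.4 ± 32.3 (SD, n = 8) and 78.9 ± 23.2 (SD, n = 7) CPM. let-7e was lower, at 1394 ± 460.2 (SD, n = 7), 3207 ± 421 (SD, n = 8) and 2777 ± 363 (SD, n = 7) CPM. These 4 passed the edgeR test against both breeds and went the same way in 7 of 7 Hampshire libraries. Other measures of the libraries, examined after the calls were seen, differed as well. The mean read length was 21.8 nt ± 0.0586 (SD, n = 7) against 21.9 nt ± 0.0378 (SD, n = 8) in Large White and 21.9 nt ± 0.0397 (SD, n = 7) in Pietrain, and unnamed sequences held 0.0851% ± 0.0532 (SD, n = 7) of reads against 0.0426% ± 0.0144 (SD, n = 8) and 0.0423% ± 0.0204 (SD, n = 7). The exact two-sided permutation p-values against Large White and Pietrain were 0.00513 and 0.00641 for the length (both 0.0128 adjusted over 4 tests) and 0.0196 and 0.0385 for the unnamed share (0.0261 and 0.0385 adjusted). These comparisons did not weight thick and thin fat equally. Pooled over reads, the unnamed share was 0.0902% in Hampshire thick and 0.0407% in Hampshire thin fat. In thick and thin fat it was 0.0398% and 0.0442% in Large White and 0.0377% and 0.0351% in Pietrain. The higher share was thus one of Hampshire thick fat only, where replicate 2 had 0.192%. The liver miRNA miR-122 averaged 6089 ± 7959 (SD, n = 7) CPM in Hampshire, 779 ± 1231 (SD, n = 8) in Large White and 1684 ± 2783 (SD, n = 7) in Pietrain, differences that did not pass the test. miR-192, found in liver and gut, had counts above 0 in 4 Hampshire libraries only. Both count as lost by the definition used here, miR-192 in 18 libraries and miR-122 in 2. For miR-192 the expected count rests on the 4 Hampshire libraries with reads alone. The definition thus cannot tell a loss from a true absence in the other 18. These values of 0 neither show nor exclude a difference of tissue. Without the 2 libraries richest in miR-122, both Hampshire, edgeR called 32 miRNAs against Large White, 21 of the original 28 among them, and 32 against Pietrain, 25 of the original 32 among them.

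**Figure D4:**
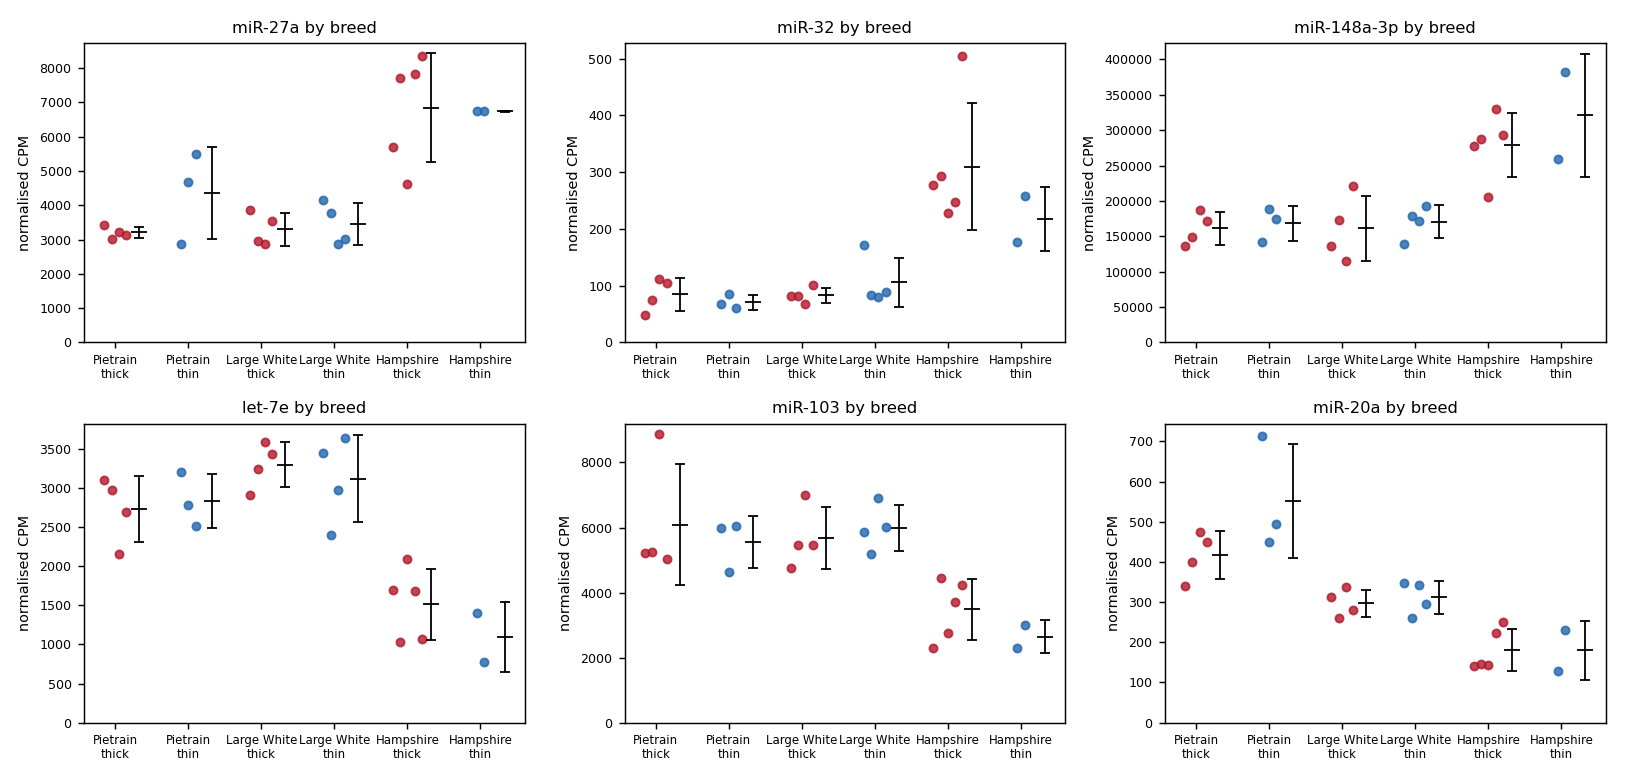
Normalised CPM (y axis, linear from 0) of miR-27a, miR-32, miR-148a-3p, let-7e, miR-103 and miR-20a in the 6 groups of breed and fat class (x axis). Points are libraries and bars the group mean and SD; mean miR-148a-3p is 291033 CPM over Hampshire libraries and 166109 CPM over Large White libraries.

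Against Large White, edgeR called 28 of 182 miRNAs, 15 higher and 13 lower in Hampshire. The higher ones were led by miR-27a (log2 fold change 0.98 ± 0.15, SE), miR-151-3p (0.66 ± 0.10), miR-32 (1.44 ± 0.24) and miR-9 (1.43 ± 0.25), with edgeR adjusted p-values from 3.6e-04 to 6.4e-04. miR-148a-3p (0.82 ± 0.15), miR-532-5p, miR-186 and miR-455-5p (0.95 ± 0.18) followed. The lower ones were led by let-7e (-1.32 ± 0.20), miR-103 (-0.97 ± 0.18), miR-140-3p (-0.70 ± 0.14) and miR-20a (-0.79 ± 0.18), then miR-365-3p and let-7f-5p. miR-145-5p and miR-145-3p, lost in 4 Hampshire libraries, were called as well. With upper quartile scaling the split was 7 higher and 26 lower, with library totals only 10 and 28, and the median of all miRNAs moved from -0.03 to -0.35 and -0.31. DESeq2 called 48. Without Hampshire thin fat replicate 2, edgeR called 19, and let-7f-5p and both arms of miR-145 no longer passed; without Hampshire thin fat replicate 1, miR-365-3p did not. miR-151-3p, miR-532-5p and miR-186 missed the threshold with upper quartile scaling, both arms of miR-145 with limma-voom, miR-140-3p with a GC and length trend removed, and miR-20a and miR-365-3p without the 2 libraries richest in miR-122.

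The let-7 family, miRNAs that restrain proliferation and are linked to glucose metabolism, was lower in Hampshire than in Large White by its median. That sign held under each of 4 scalings, which adds little, since upper quartile scaling and library totals lowered the median of all miRNAs. Of 8 members 3 fell, let-7e, let-7f-5p and let-7g, 0 rose and 5 did not pass, with let-7a at -0.49 ± 0.22 and let-7i-5p at 0.22 ± 0.22 (median -0.48, camera adjusted p = 0.0223). With an estimated correlation the adjusted p was 0.832, and adjusted over the list alone 4 members were called. Of 17 adipogenesis promoters 1 rose, miR-148a-3p, and 3 fell, miR-103, miR-20a and miR-17-5p, and 4 were called adjusted over the list alone. Of 18 adipogenesis repressors 1 rose, miR-27a, and 4 fell, the 3 let-7 members and miR-145-5p, and 8 were called adjusted over the list alone. Both arms of miR-145 were lost in 4 Hampshire libraries, so a fall of either, here and below, cannot be told apart from those losses. Of 10 thermogenic miRNAs 2 rose, miR-32 and miR-455-5p, and 1 fell, miR-365-3p, with 4 called adjusted over the list alone. In the miR-23/24/27 clusters miR-27a and miR-24-3p (0.45 ± 0.11) rose. Among markers of other cells, miR-152 and both arms of miR-145 fell of 7 for smooth muscle and stroma, 1 of 4 endothelial markers rose, miR-101 (0.59 ± 0.20), and 0 of 3 for skeletal muscle, 0 of 3 for red blood cells, 0 of 4 for epithelium, 0 of 5 for leukocytes and 0 of 10 linked to inflammation were called. These lists, all but let-7, had camera adjusted p-values of 0.0891 or more. Of the lists with 2 members, the nerve marker miR-9 rose and miR-128 had 0.32 ± 0.25, while of the liver markers 0 were called, with miR-122 at 3.65 ± 1.58 (edgeR adjusted p = 0.124).

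Against Pietrain, edgeR called 32 of 182 miRNAs, 19 higher and 13 lower in Hampshire. miR-455-5p (1.36 ± 0.19, SE), miR-32 (1.75 ± 0.26), miR-186 (0.94 ± 0.16) and miR-24-1-5p (0.93 ± 0.16) led the higher ones, followed by miR-27a, miR-148a-3p (0.87 ± 0.16), miR-1271-5p and miR-381-3p. miR-140-3p (-1.14 ± 0.15), miR-20a (-1.41 ± 0.19), miR-17-5p (-1.15 ± 0.21) and let-7e (-1.07 ± 0.20) led the lower ones, with edgeR adjusted p-values from 5.9e-05 to 8.6e-04, and miR-103 and let-7f-5p followed. The let-7 family was lower, with 3 of 8 members called, the same 3 as against Large White (median -0.45, camera adjusted p = 0.0223, and an adjusted p of 0.607 with an estimated correlation). Adjusted over the list alone, 3 let-7 members, 2 of the miR-17-92 cluster (miR-20a and miR-17-5p), 6 adipogenesis repressors and 4 promoters were called, with 4 thermogenic miRNAs, 3 of smooth muscle and stroma, 2 red blood cell and 2 epithelial markers. Of 3 skeletal muscle markers 1 rose, miR-499-5p (1.24 ± 0.26), of 4 epithelial markers 1 rose, miR-182 (1.22 ± 0.37), and of 2 nerve markers both rose, miR-9 and miR-128. The liver marker miR-122 had 2.21 ± 1.60 (edgeR adjusted p = 0.386). With upper quartile scaling the split was 11 higher and 28 lower and with library totals only 12 and 22. DESeq2 called 47 and limma-voom 27, without either arm of miR-145, and let-7f-5p did not pass without Hampshire thin fat replicate 2.

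The deposited comparisons in Pietrain and Hampshire were recovered from the labels. Across sequences, a DESeq2 refit (thick minus thin) had r = -1.0 with the authors' deposited table (thin minus thick) in both breeds, and all 89 Pietrain calls and the 1 Hampshire call were among the calls of the refit. In Large White the authors' deposited table called 0 sequences, and a refit by the labels called 2. Sequences of 1 table are not independent replicates.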

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

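The tests of lost arms, of calls made of lost miRNAs, of the share of U1G reads and of batch labels were chosen after the results were seen; the others were planned before their results were seen. Of 201 groups of named values examined, 13 held a library far from the others of its group, against about 1 in 20 by chance. In Large White thick fat, replicate 1 stood apart with 205993 CPM of miR-143-3p, 14731 of miR-125b and 437 of miR-145-3p, all above the others, and replicate 2 with 67755 CPM of let-7f-5p. In Large White thin fat, replicate 1 had 91.4 CPM of miR-9 and 171 of miR-32, replicate 2 had 569 CPM of miR-193a-5p, below the others, and replicate 3 had 13.7 CPM of miR-19a against 0. In Pietrain thick fat, replicate 3 had 8861 CPM of miR-103 and 839 of miR-365-3p. In Hampshire thick fat, replicate 5 had 504 CPM of miR-32, replicate 1 had 413 of miR-24-1-5p and replicate 3 had 18.6 of miR-19a against 0. Outside the named miRNAs, the unnamed sequence GCAUUGUGGUUCAGUGGUAGAAUU held 9452 reads over the 22 libraries.

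The first pattern weighed was the absence of whole miRNAs: 36 miRNAs were at 0 in libraries where at least 100 reads were expected. Low depth was largely set aside by the definition, since a loss counts only where at least 100 reads were expected. The share of eligible miRNAs lost rose with the library total (Spearman rho = 0.592, permutation p = 0.00451; Pearson r = 0.634, permutation p = 0.00151; r = 0.497 without the 2 totals farthest from the median), with rho of 0.775 within Pietrain, 0.190 within Large White and 0.857 within Hampshire. Weaker miRNAs are eligible only in deep libraries, so part of this rise may come from the definition, and it decides nothing about depth. Loss of a whole hairpin in the authors' annotation stays open: counting each lost arm, the other arm was at 0 too in 83.9% of 112 cases, and counting each hairpin and library once in 77.8% of 81, as for miR-142, miR-145 and miR-199, while miR-181a kept its other arm in 15 of 15 libraries. Whether miR-181a and its other arm come from 1 hairpin only was not checked, so those 15 cases may not count against hairpin loss. Among the 36, miR-429 and miR-200b share a leading sequence. miR-429 had reads in 18 libraries, miR-200b in 3 and both in 0, so a loss of either may be one of name only. Fat class stays open as well, with a smallest adjusted p of 1 over 35 exact Mantel-Haenszel or Fisher tests, which does not show that the classes lost miRNAs alike.

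The second pattern was the U1G sequences of Pietrain, higher in thick than in thin libraries and 25 of the 89 deposited Pietrain calls. An error shared by the miRNAs of a library may account for them but stays open: the library took 25.1% of the variance of the log2 share over 20 miRNAs in Pietrain and 78.1% over the 18 with reads of another first base, but only 0.578% lay between libraries of 1 fat class, and fat class would give the same values. Fat class acting alike in the 3 breeds is argued against, since over the summed reads of the 18 the highest log2 ratio of a thick to a thin library was 0.082 in Hampshire against a lowest of 1.57 in Pietrain. A first form of that test, which asked the same of Large White with 2 libraries exchanged, was undecided (1.72, from a library with 15 U1G reads), as was the difference of medians there, -0.13 ± 0.12, whose bound was given up after it was seen because most medians lie at 0. An effect of fat class in Pietrain alone cannot be told apart from a separate run or lane, because no labelled batch was shared by breeds (0) and none divides the Pietrain libraries.

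The third pattern was the set of miRNAs called between Hampshire and the other breeds. GC content and length as the whole cause are argued against, since 88.3% of the calls stayed past the threshold with a GC and length trend removed per library. Loss of miRNAs in single libraries is argued against for most, since 13.3% of the calls were miRNAs lost in some library. A difference between library batches may underlie the calls and cannot be told apart from breed, because 0 labelled batches are shared by 2 breeds, and a breed difference stays open, as untested. Chance is argued against for the number of calls of Hampshire minus Large White (28, against 11 in the highest of the other splits, 1 of 100 splits, the real one, reaching 28). The same holds for Hampshire minus Pietrain (32 against 24, 1 of 100 splits). With 100 splits chance is not excluded, and the splits say nothing about single miRNAs.

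For the comparisons with 0 calls the splits decide nothing about chance, since no split can give fewer than 0. The highest other split gave 2 in Pietrain (35 of 35 splits gave at least 0), 1 in Large White (35 of 35), 1 over all breeds (100 of 100), 8 for the interaction (100 of 100) and 0 for Pietrain minus Large White (100 of 100). Whether a structure of the samples underlies the split with 8 was not tested. No splits were drawn for thick minus thin fat within Hampshire, where thin fat has 2 libraries.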

How the results depend on the processing

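The exchange of the Large White libraries, the fits without lost miRNAs, without the 2 libraries richest in miR-122 or without the 2 shallowest, and the removal of a GC and length trend were chosen after the data were seen. Of the values compared with their alternatives, 2069 values of named miRNAs kept their sign and their side of the threshold, whatever their change in size. Of the counts, 222 stayed within 1.5 times of the main count, and 30 moved further, rises from 0 and falls to 0 among them. Of the named miRNAs, 8 values newly passed the threshold, 15 no longer did and 21 changed sign. Of these changes the cause was not tested. DESeq2 called 1 miRNA in Pietrain, 3 in Hampshire, 1 over all breeds, 2 in the interaction, 4 for Pietrain minus Large White and 48 for Hampshire minus Large White. Single sequences gave 65 calls in Pietrain, 1 over all breeds, 18 for Pietrain minus Large White, 454 for Hampshire minus Large White and 515 for Hampshire minus Pietrain. Over all breeds 1 miRNA was called with RLE size factors and 1 with upper quartile scaling, miR-9 both times. The interaction gave 2 without the 2 libraries richest in miR-122, and Pietrain minus Large White 1 without the 2 shallowest libraries. List counts over all breeds (1 with camera) were 0 with an estimated correlation, 0 with fry and 0 with the Large White replicates exchanged; for Hampshire minus Large White (1) they were 0 and 2, and for Hampshire minus Pietrain (1) 0 and 6. Leaving out single libraries gave 0 to 2 calls in Pietrain, 0 to 1 in Large White, 0 to 1 in Hampshire, 0 to 1 over all breeds, 0 to 2 in the interaction, 0 to 1 for Pietrain minus Large White, 19 to 36 for Hampshire minus Large White and 26 to 37 for Hampshire minus Pietrain. Without either Hampshire thin library, the other is assumed to vary like the other groups. With the Large White exchange the Large White log2 fold changes turned to -0.24 for miR-27a-5p, -0.10 for miR-125b, 0.25 for miR-146a-5p, 0.35 for miR-9 and 0.21 for miR-499-5p, and over all breeds to -0.034 for miR-26a. Over all breeds miR-10b turned to -0.020 with upper quartile scaling, -0.015 with limma-voom, -0.0076 without Pietrain and -0.018 without the 2 libraries richest in miR-122, and ranged from -0.053 to 0.059 without single libraries. miR-99a was -0.022 without Pietrain. miR-143-3p was 0.23 without Hampshire, 0.058 without the 2 libraries richest in miR-122, and -0.39 to 0.033 without single libraries, and miR-26a was -0.0067 to 0.095 without single libraries. The median of all miRNAs in Hampshire thick minus thin fat moved to -0.21 with upper quartile scaling and 0.19 with library totals only, and for Hampshire minus Pietrain to -0.29 and -0.24. No paired analysis was possible because the labels give no replicate numbers that pair libraries across groups. Depth limits miRNAs of few reads, since sequences under 6 reads are at 0.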

Other observations

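The liver miRNA miR-122 varied widely between libraries, from 0 CPM in Pietrain thick fat replicate 3 and Large White thick fat replicate 1 to 21383 CPM in Hampshire thin fat replicate 1 and 12549 CPM in Hampshire thick fat replicate 3. miR-192, found in liver and gut, had counts above 0 in 4 of 22 libraries, all Hampshire, with 5334 CPM in thin fat replicate 1 and 8665 CPM in thick fat replicate 3. It counts as lost in the other 18 libraries, as miR-122 does in the 2 libraries at 0. The skeletal muscle miRNA miR-206 ranged from 27.9 CPM in Large White thin fat replicate 4 to 1502 CPM in Hampshire thick fat replicate 4. These values were picked after they were seen.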
